A study of Mus musculus with 12 samples.

How the data were processed

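RNA from 4 groups of primary mouse embryonic fibroblasts, wildtype or Rb null and untreated or treated with 16 µM cisplatin for 24 h, was hybridized to 12 Affymetrix mouse expression arrays, 3 per group, from 6 µg of RNA each. The deposited values are signal intensity per probe set, and per the labels they were made with MAS5, the Affymetrix software that averages the probes of a probe set on each array by itself. The version of that software, its scaling target and detection calls are not stated in the labels or the table used here. The values are linear and never negative, and the mean of each array after trimming 2% at each end was 500.1 or 500.2, so the arrays had been scaled to the same mean and were used on that scale. Without detection calls no background level could be set for single probe sets.

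The values were converted to log2 after adding 10.4, the 10th percentile of all deposited values, which understates fold changes of weak genes. Of 22690 probe sets, 64 controls were left out, and of the remainder the 40% with the lowest mean log2 signal, since weak signals vary most between arrays; 13575 were tested. The platform annotation gave a single gene symbol for 20393 probe sets, several genes for 691 and was without an entry for 1555. Results by gene use 1 probe set per gene, which left 7945 genes. Probe sets with a suffix that marks cross-hybridization (_x_at, _f_at, _r_at, _i_at or _g_at) were used only where a gene had no other. The one with the highest mean was then taken, and _s_at probe sets were allowed.

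Groups were taken from the sample labels. A mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend in the prior variance; 8 residual and 6.09 prior degrees of freedom). The contrasts were Rb null minus wildtype without and with cisplatin, cisplatin minus untreated in each genotype, the difference between the cisplatin effects, and the averages of genotype and of cisplatin. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over the 13575 tests of a contrast and a change of at least 1.5-fold; the tests of limma and camera are two-sided, and those with regroupings, random lists and gene windows one-sided. Standard errors are those of limma, which pools the spread over the 4 groups. No replicate block was used, since the labels do not say that hybridizations with the same number belong together.

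The 27 gene lists covered cell cycle, DNA damage, stress, immune, matrix and metabolic genes and markers of other cell types, and were written from general knowledge before the data were examined, as were the contrasts, the thresholds and the alternatives, except where stated. Lists with at least 5 tested members, 24 in number, were tested against all other genes with camera of limma at the preset correlation between genes of 0.01 and, beside it, with an estimated correlation, with adjustment over 120 tests (24 lists in 5 contrasts). With the preset correlation 57 of these passed, and 28 with an estimated correlation. Among lists that lost calls, some estimates lay above the preset value, such as 0.14 for ribosomal proteins. Others lay below it, such as -0.0326 for inflammatory genes and -0.0475 for chondrocyte and bone markers. A call lost with an estimated correlation therefore does not by itself show that the genes of a list are correlated. The erythroid list had 0 tested members, the adipocyte list 4 and the sex-linked list 1.

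Genes to be named were chosen by rule. They are, for each contrast, the 8 with the largest rise and the 8 with the largest fall among called genes whose arrays in the 2 groups did not overlap (6 and 6 for the difference of responses), without provisional symbols. To these were added up to 4 called members of each list with the largest change, or every called member where 5 or fewer were called, Rb1 and all sex-linked markers. The text gives a selection of these, and each gene named as higher, lower, risen or fallen was called.

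The model was tested on simulated data of the same size, with 200 of 13575 probe sets changed in 5 runs. It recovered 33.2% of 1.5-fold, 86.4% of 2-fold and 99.6% of 4-fold changes, with on average 4.2 false calls among 162.2. The simulated spread was that between arrays of a group, so these figures leave out differences between cultures. Far fewer probe sets were changed than were called in the data, so the figures may not carry over. A 1.5-fold change lies at the minimum for a call, which by itself keeps its recovery low. The alternatives were other pseudocounts (1 and 45.8), no filter and a filter at 60%, quantile normalization, median centring, no variance trend, other fold minimums, only the 2 groups compared, and a replicate block. Further ones were leaving out each array in turn, each group as a single sample, all probe sets of the listed genes, and, added after the sex-linked transcripts were seen, a fit without the untreated wildtype group. A table of mouse genes was used to update gene symbols and to match the names on the lists. Its positions were used only to find the genes nearest to Rb1.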

Results

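Gene expression was measured in primary mouse embryonic fibroblasts (MEFs), connective tissue cells grown from 13.5-day embryos and used at passage 2. The cells were wildtype or lacked the retinoblastoma gene Rb1 (Rb null). The retinoblastoma protein binds E2F transcription factors and restrains entry into S phase. Cells of each genotype were left untreated or were exposed for 24 h to 16 µM cisplatin, a platinum compound that crosslinks DNA. The 4 groups were each measured on 3 Affymetrix arrays, 12 arrays in total, and each array gave a signal for 22690 probe sets. Of these, 13575 were tested, which stood for 7945 genes. The number of arrays limits the precision. The design describes 4 RNA samples that were each hybridized 3 times, so the p-values may measure only the spread between hybridizations of the same RNA. Signals are given as mean ± SD and log2 changes as estimate ± standard error, with n = 3 hybridizations per group throughout.

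Arrays of the same group were much alike. The log2 signals of 2 arrays correlated across probe sets at 0.981 to 0.992 within a group (12 pairs) and at 0.806 to 0.952 between groups (54 pairs). The first principal component held 64.4% of the variance and separated treated from untreated arrays. It placed the cisplatin-treated Rb null arrays (58.4 to 59.2) farther from the untreated arrays (-49.4 to -34.6) than the cisplatin-treated wildtype arrays (24.4 to 25.1). The second component held 15.5% and separated the genotypes within each treatment.

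**Figure D1:**
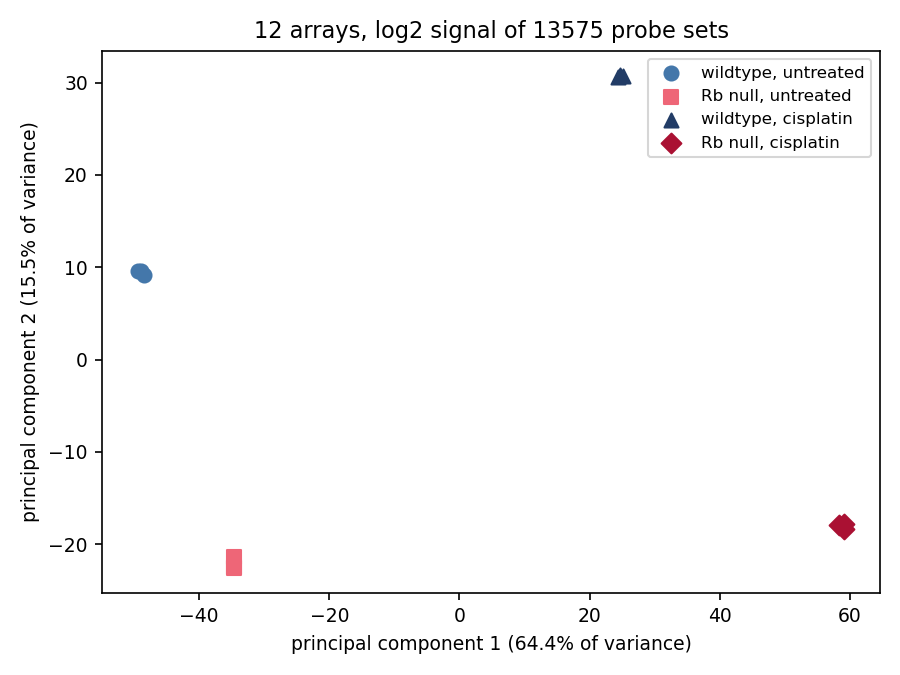
Scores of the 12 arrays on the first principal component (x axis, 64.4% of the variance) and the second (y axis, 15.5%) of the log2 signals of the tested probe sets, without units, where each point is an array coloured by group. The 3 arrays of each group lie close together, and cisplatin-treated arrays lie to the right of untreated ones.

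Rb1 itself was measured by 1 probe set, and whether this lies within the deleted part of the gene is not known. Its signal was 459.7 ± 35.4 in untreated wildtype and 94.0 ± 9.99 in untreated Rb null cells, a 4.51-fold lower level (log2 -2.17 ± 0.14, adjusted p = 3.54e-08). After cisplatin it was 383 ± 60.1 in wildtype and 89.6 ± 14.5 in Rb null cells (log2 -1.98 ± 0.14, adjusted p = 9.41e-08). Cisplatin itself gave Rb1 log2 values of -0.27 ± 0.14 in wildtype and -0.0673 ± 0.14 in Rb null cells, neither of which passed the test.

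Transcripts of the sex chromosomes set the untreated wildtype arrays apart from the other 9 arrays. Xist, the RNA that silences an X chromosome in female cells, had a signal of 132 ± 26.7 on untreated wildtype arrays, against 3139 ± 329 in untreated Rb null, 2379 ± 198 in cisplatin-treated wildtype and 3443 ± 281 in cisplatin-treated Rb null cells. The Y-linked Eif2s3y, a translation factor gene, had a signal of 478 ± 7.9 on untreated wildtype arrays and group means of 1.27 to 6.63 elsewhere. Kdm5d, a Y-linked histone demethylase gene, was at 193 ± 18.5 on its probe set with the largest difference, against 6.83 to 21.5 in the other groups, and the Y-linked Uty was at 199 ± 16.6 against 23.0 to 27.4. The Y-linked Usp9y was low in every group (41.9 to 68.0). Each comparison that uses the untreated wildtype group therefore also sets RNA with Y-linked transcripts against RNA with Xist.

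**Figure D2:**
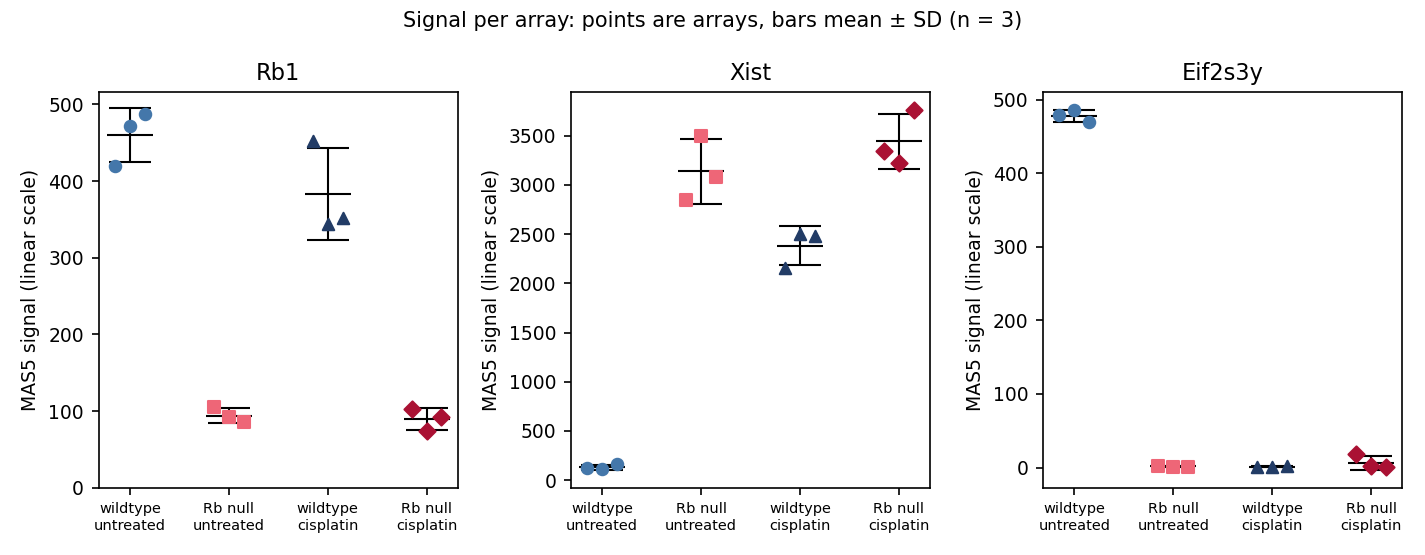
Signal (MAS5 intensity, linear y axes starting at 0) of Rb1, Xist and the Y-linked Eif2s3y in the 4 groups, where points are the 3 arrays of a group and bars with error bars are mean ± SD. Rb1 is low in both Rb null groups, while Xist is low and Eif2s3y high in the untreated wildtype group alone.

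The comparison of untreated Rb null with untreated wildtype cells asked which transcripts differ with the loss of Rb1 in unstressed cultures. Cell cycle genes were higher in Rb null cells as a body: all 43 measured E2F targets of the G1/S transition and of DNA replication passed the test as higher, with a median log2 difference of 1.5. So did 41 of the 42 genes of G2/M and mitosis, with a median of 1.93. Of these 42, 39 had their lowest group mean on the untreated wildtype arrays, so genotype and that culture cannot be told apart here. In the genotype comparison after cisplatin, which does not use that group, the medians were 0.86 for E2F targets and 0.42 for G2/M. Tk1, which encodes thymidine kinase, had a signal of 277 ± 59.2 in wildtype and 1596 ± 128 in Rb null cells (5.67-fold). Ccne2, whose product cyclin E2 drives entry into S phase, was 5.46-fold higher. The replication licensing gene Cdc6 and the DNA polymerase gene Pola1 were higher by log2 2.62 ± 0.39 and 2.43 ± 0.15. Of the mitotic genes, the spindle checkpoint kinase gene Bub1b (log2 2.42 ± 0.14), the centromere histone gene Cenpa (2.42 ± 0.14), the proliferation marker Mki67 (2.35 ± 0.0916) and the mitotic kinase gene Plk1 (2.34 ± 0.12) differed most.

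Set against the other genes with limma's camera, both lists passed (E2F targets, adjusted p = 2.94e-36; G2/M, 1.57e-37), and both passed with an estimated correlation (adjusted p = 3.33e-05 and 3.23e-05). Among 36 DNA repair genes 17 were higher and 0 lower, led by the mismatch repair gene Msh6 (log2 1.73 ± 0.0738) and the homologous recombination gene Brca1 (1.66 ± 0.11). This list had adjusted p = 1.05e-07, and 0.002 with an estimated correlation. The 25 regulators of the Rb, E2F and G1 pathway, of which 5 are on another list, held 11 higher and 2 lower members (adjusted p = 0.000125, and 0.0106 with an estimated correlation). Among the higher members were the Rb1 relative Rbl1 (log2 1.88 ± 0.12) and Rb1 was among the lower ones. Targets of p53, the transcription factor activated by DNA damage, of which 8 of 28 are on another list, were higher for 7 and lower for 1 (adjusted p = 0.00384, and 0.0271 with an estimated correlation). With each array centred on its median, 5 were higher and 2 lower. The desmosome gene Perp was higher (log2 1.04 ± 0.14) and the apoptosis gene Pmaip1 lower (-1.18 ± 0.11).

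Several stromal and immune lists shifted by less, and their calls were lost with an estimated correlation. Of 18 inflammatory cytokines and NF-kB targets 6 were lower and 1 higher, including the cytokine genes Il11 (log2 -1.58 ± 0.12), Lif (-1.34 ± 0.17) and Il6 (-1.23 ± 0.18). This list had adjusted p = 0.0146, adjusted p = 0.0587 with an estimated correlation and 0.0729 without the filter on level. Interferon response genes were higher for 3 of 22, among them Ifit2 (log2 1.20 ± 0.20) and the class I antigen gene H2-D1 (1.20 ± 0.15). This list had adjusted p = 0.00384, and adjusted p = 0.0657 with an estimated correlation. Smooth muscle and TGF-beta response genes were lower for 6 of 22, with the ligand gene Tgfb2 at log2 -1.24 ± 0.17 (adjusted p = 0.0151, and adjusted p = 0.0864 with an estimated correlation). The 41 extracellular matrix genes went both ways, 5 higher and 7 lower, from the collagen gene Col6a3 (log2 1.28 ± 0.10) to the protease inhibitor gene Timp3 (-1.11 ± 0.0980) and the microfibril gene Mfap5 (-1.20 ± 0.0739). Their list had adjusted p = 0.0146, and adjusted p = 0.222 with an estimated correlation. The calls of these last 2 lists also ended under quantile normalization (adjusted p = 0.0559 and 0.0674).

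Markers of other cell types moved with genotype as well. Skeletal muscle markers were lower for 5 of 8, including the cardiac actin gene Actc1 (log2 -1.21 ± 0.15; adjusted p = 0.00398, and adjusted p = 0.0545 with an estimated correlation). Neural markers were lower for 3 of 10, led by the brain lipid carrier gene Fabp7 (log2 -2.96 ± 0.19; adjusted p = 0.00412, and adjusted p = 0.0657 with an estimated correlation). Chondrocyte and bone markers were higher for 3 of 6, namely the collagen genes Col10a1 (log2 2.15 ± 0.20) and Col2a1 (1.27 ± 0.28) and the matrix protein gene Mgp (1.15 ± 0.0800). Their list had adjusted p = 0.0146, adjusted p = 0.0657 with an estimated correlation and 0.0553 without the filter. Macrophage and leukocyte markers were higher for 4 of 21, among them the lysozyme genes Lyz2 (log2 0.97 ± 0.0776) and Lyz1 (0.86 ± 0.0956), the latter from a probe set that can cross-hybridize. Under quantile normalization and under median centring 2 were higher, as Cd14 and Adgre1 lost their calls. The list had adjusted p = 0.0264, and adjusted p = 0.106 with an estimated correlation. The other 11 lists tested did not pass (adjusted p from 0.154 to 0.94). Among them were 39 cytosolic ribosomal protein genes and 57 respiratory chain genes, in which 0 members passed limma's test; at an unadjusted p under 0.05, 3 and 21 of them did. Under quantile normalization and median centring 1 ribosomal gene passed as lower.

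Outside the lists, the skin envelope gene Lce1f differed most, with 2775 ± 169 in wildtype and 77.6 ± 12.3 in Rb null cells (log2 -4.99 ± 0.11). In all, 1678 probe sets (12.4%) passed, 1042 higher and 636 lower in Rb null cells, which stood for 641 and 404 genes. With each array centred on its median, 56.4% of 1689 in place of 62.1% were higher. Adjusted over the list alone, the counts were the same for 24 of the 27 lists. ER stress genes then had 4 lower members in place of 3, skeletal muscle markers 6 in place of 5, and chondrocyte and bone markers 4 higher in place of 3. Xist was higher in Rb null cells by log2 4.48 ± 0.12, so the groups differ in sex-linked transcripts as well as in genotype.

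The comparison of Rb null with wildtype cells after cisplatin asked which transcripts differed with genotype in damaged cells. The E2F targets were again higher in Rb null cells, 35 of 43 against 1 lower, with a median log2 difference of 0.86. The largest were Ccne2 (log2 1.91 ± 0.13), the primase gene Prim1 (1.75 ± 0.0928), Cdc6 (1.73 ± 0.39) and the origin recognition gene Orc1 (1.66 ± 0.19). Mitotic genes were higher for 15 of 42 and lower for 0, by a median of 0.42. Mki67 was at log2 1.45 ± 0.0916 and the anaphase activator gene Cdc20 at 1.32 ± 0.0814. Extracellular matrix genes were lower for 23 of 41 and higher for 1, by a median of -0.71. The proteoglycan gene Lum had a signal of 960.5 ± 43.9 in wildtype and 93.2 ± 9.24 in Rb null cells, and the collagen genes Col11a1 (log2 -1.83 ± 0.0731) and Col3a1 (-1.66 ± 0.0954) were lower too. Macrophage and leukocyte markers were lower for 13 of 21 and higher for 0, by a median of -1.05. The complement gene C1qa was at log2 -2.39 ± 0.15, the lysosomal protease gene Ctss at -2.36 ± 0.14 and Lyz2 at -1.93 ± 0.0776.

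These lists passed camera with both the preset and an estimated correlation: E2F targets, adjusted p = 3.96e-18 and 0.00025; G2/M, 1.59e-07 and 0.002; extracellular matrix, 7.67e-09 and 0.0271; macrophage markers, 4.05e-06 and 0.0114. The same held for DNA repair, with 11 of 36 higher and 2 lower (adjusted p = 0.000209 and 0.0106), where the uracil glycosylase gene Ung was at log2 1.40 ± 0.15. It held for p53 targets too, with 7 of 28 higher and 0 lower (adjusted p = 2.32e-05 and 0.00679). The death receptor gene Fas was at 1.49 ± 0.15 and the growth arrest gene Gadd45a at 1.01 ± 0.17. Adjusted over the list alone, the counts were the same for 25 of the 27 lists. DNA repair then had 3 lower members and skeletal muscle 1 higher in place of 0.

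Of the interferon response genes 7 of 22 were higher and 3 lower: Gbp3 was at log2 2.61 ± 0.28 and Gbp2 at 2.30 ± 0.14 (list adjusted p = 0.00819, and adjusted p = 0.0859 with an estimated correlation). Immediate early and short-lived transcripts, 5 higher and 2 lower of 30, included Fos (log2 0.83 ± 0.12) and, lower, Klf2 (-1.61 ± 0.14). This list had adjusted p = 0.00487, and adjusted p = 0.101 with an estimated correlation. The Rb, E2F and G1 regulators, 9 higher and 3 lower of 25, included the kinase gene Cdk2 (log2 1.07 ± 0.10) and, lower, Rb1 and its relative Rbl2 (-1.02 ± 0.14). Their list had adjusted p = 0.0388, and adjusted p = 0.0859 with an estimated correlation. The call also ended under quantile normalization (adjusted p = 0.0559) and with all probe sets of the listed genes (0.0604). Cytosolic ribosomal protein genes lay slightly higher as a list (median log2 0.21, adjusted p = 0.00052), although 0 of 39 members passed limma's test as higher and 2 as lower (Rpl22 and Rps25, which lost its call under median centring). The call was lost with an estimated correlation (adjusted p = 0.196) and under quantile normalization (adjusted p = 0.354). The 3' control probe set of 18S ribosomal RNA was higher in these Rb null than in these wildtype samples (383 ± 91.7 against 213.5 ± 29.2). The 14 other lists tested did not pass (adjusted p from 0.0604 to 0.949). Among them was the inflammatory list, in which the chemokine genes Ccl5 (log2 2.51 ± 0.21) and Cxcl1 (2.13 ± 0.14) were higher; it passed without the filter on level (adjusted p = 0.0386), and the glycolysis list with all probe sets of the listed genes (0.00196).

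Outside the lists, the interferon-inducible gene Ifi202b had 121 ± 9.81 in wildtype and 2823 ± 159 in Rb null cells (log2 4.43 ± 0.0911), and the growth factor gene Igf2 801 ± 84.3 and 5464 ± 269 (log2 2.76 ± 0.0744). On the lower side, Rpgrip1, a gene of the photoreceptor cilium, had 2835 ± 99.6 and 104 ± 30.1 (log2 -4.68 ± 0.18), and the extracellular superoxide dismutase gene Sod3 1010.0 ± 20.9 and 61.9 ± 10.8 (log2 -3.83 ± 0.19). In all, 3002 probe sets (22.1%) passed, 1250 higher and 1752 lower, for 768 and 1059 genes. The higher share of 41.6% became 51.6% of 2966 with each array centred on its median. Xist was at log2 0.53 ± 0.12 (adjusted p = 0.00187), below the 1.5-fold minimum, and passed as higher under median centring, and Y-linked transcripts were low in both groups. Genotype differences without and with cisplatin correlated across 7945 genes at r = 0.296 (Spearman's rho 0.277), where genes are not independent replicates. Of the genes called in both, 250 were higher and 123 lower in both, against 62 and 53.8 by chance, and 84 were called in opposite directions.

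Cisplatin-treated and untreated wildtype cells were compared for the response to the drug in cells with Rb1. Targets of p53 rose, 17 of 28 against 0 that fell, by a median log2 change of 0.79. Perp rose by 2.40 ± 0.14, the xylulose reductase gene Dcxr by 2.31 ± 0.0721, the autophagy and apoptosis gene Trp53inp1 by 1.98 ± 0.0971 and the peptide transporter gene Tap1 by 1.81 ± 0.0972. Cdkn1a, the p53 target that encodes the CDK inhibitor p21, was looked up after the values were seen, and had a log2 value of 0.40 ± 0.0556 that passed on adjusted p but was below the 1.5-fold minimum. Cell cycle genes were higher after cisplatin, with 0 lower in either list: 36 of 43 E2F targets (median log2 1.10), such as the licensing gene Cdt1 (1.61 ± 0.0642), and 29 of 42 genes of G2/M and mitosis (median 0.85), such as Cdc20 (1.67 ± 0.0814). Genes of the smooth muscle and TGF-beta response list fell, 14 of 22 against 0 that rose, by a median of -0.80, with the calponin gene Cnn1 at -2.64 ± 0.0946 and the smooth muscle actin gene Actg2 at -2.56 ± 0.0738.

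Each of these 4 lists passed with the preset and with an estimated correlation (p53 targets, adjusted p = 1.23e-05 and 0.00634; E2F targets, 2.79e-13 and 0.000654; G2/M, 2.72e-09 and 0.00123; smooth muscle, 4.88e-08 and 0.00605). So did the oxidative stress and metallothionein genes, of which 8 of 20 rose and 0 fell (adjusted p = 0.000129 and 0.0252), led by the metal-binding Mt2 (log2 1.91 ± 0.17) and Mt1 (1.89 ± 0.0893). The ER stress and amino acid response list fell, 14 of 28 against 4 that rose (adjusted p = 0.000557 and 0.0153). Its members Psph (log2 -1.77 ± 0.12) and Mthfd2 (-1.66 ± 0.0724) fell, while the stress transcription factor gene Atf3 rose (3.17 ± 0.29). Adjusted over the list alone, the counts in both cisplatin comparisons were the same as over all probe sets for all 27 lists. Signs of RNA composition moved with treatment. The 3' control probe set of 18S ribosomal RNA went from 105.7 ± 14.5 in untreated to 213.5 ± 29.2 in cisplatin-treated wildtype samples. The ratio of the 3' to the 5' actin control was 1.14 ± 0.0265 and 1.22 ± 0.0289.

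Other lists passed with the preset correlation alone. Extracellular matrix genes fell for 20 of 41 and rose for 4, from the collagen genes Col8a1 (log2 -2.89 ± 0.0649) and Col5a1 (-2.40 ± 0.0854) to the collagenase gene Mmp13, which rose from 61.0 ± 13.2 to 1006 ± 39.8. This list had adjusted p = 3.1e-06, and adjusted p = 0.0587 with an estimated correlation. Immediate early transcripts rose for 14 of 30 and fell for 2, with Fos at log2 2.82 ± 0.12 and Egr1 at 2.69 ± 0.12 (adjusted p = 0.00487, and adjusted p = 0.101 with an estimated correlation). Heat shock genes rose for 5 of 17, among them Hspa1a (log2 2.51 ± 0.13; adjusted p = 0.0244, and adjusted p = 0.0721 with an estimated correlation). DNA repair genes rose for 11 of 36 and fell for 1, with Msh6 at 2.26 ± 0.0738 (adjusted p = 0.0305, and adjusted p = 0.0657 with an estimated correlation). Macrophage and leukocyte markers rose for 7 of 21 and fell for 2, with Lyz2 going from 1124 ± 124 to 4174 ± 254 (adjusted p = 0.0443, and adjusted p = 0.137 with an estimated correlation, and 0.0729 without the filter on level). Neural markers fell for 6 of 10, including the adhesion gene Ncam1 (log2 -3.28 ± 0.13; adjusted p = 0.00384, and adjusted p = 0.0657 with an estimated correlation). The other 12 lists tested did not pass (adjusted p from 0.0604 to 0.86). Of these, interferon genes passed under quantile normalization (adjusted p = 0.0421), without the filter (0.0231) and with all probe sets (0.00644). The Rb, E2F and G1 regulators did so without the filter (0.0296) and with all probe sets (0.0484), and skeletal muscle markers without the filter (0.0132). The median and the test of the inflammatory list pointed up and its mean, -0.00305, down.

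Outside the lists, the monoacylglycerol lipase gene Mgll fell from 4985 ± 273 to 84.4 ± 21.3 (53.6-fold) and the protease gene Adam12 from 1960.0 ± 207 to 111 ± 9.26, whereas Rpgrip1 rose from 50.9 ± 6.79 to 2835 ± 99.6. The water channel gene Aqp1 rose from 53.5 ± 6.30 to 1243 ± 29.6. In all, 3626 probe sets (26.7%) passed, 1838 higher and 1788 lower, for 1175 and 1009 genes. The higher share of 50.7% became 56.2% of 3690 under median centring. Xist rose by log2 4.08 ± 0.12 and the Y-linked Eif2s3y went from 478 ± 7.9 to 1.27 ± 0.981, so the 2 wildtype groups differ in sex-linked transcripts as well as in treatment.

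Cisplatin-treated and untreated Rb null cells, both with Xist and with low Y-linked signals, were compared for the response in cells without Rb1. Targets of p53 rose, 18 of 28 against 0 that fell, by a median log2 change of 0.81, led by Perp (2.76 ± 0.14), Pmaip1 (2.47 ± 0.11), Tap1 (2.25 ± 0.0972) and Fas (2.11 ± 0.15). Genes of G2/M and mitosis fell, 20 of 42 against 1 that rose, by a median of -0.56. Those that fell included the kinetochore gene Cenpf (-2.07 ± 0.11), Plk1 (-1.64 ± 0.12) and the checkpoint kinase gene Ttk (-1.56 ± 0.14). E2F targets went both ways: 15 of 43 rose and 4 fell, by a median of 0.41 (2 fell under median centring), with Cdt1 at 1.54 ± 0.0642 and Pola1 at -2.77 ± 0.15. Extracellular matrix genes fell, 25 of 41 against 1 that rose, by a median of -0.94, among them Col11a1 (-3.27 ± 0.0731), Col8a1 (-3.11 ± 0.0649) and Col12a1 (-2.99 ± 0.0974).

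**Figure D3:**
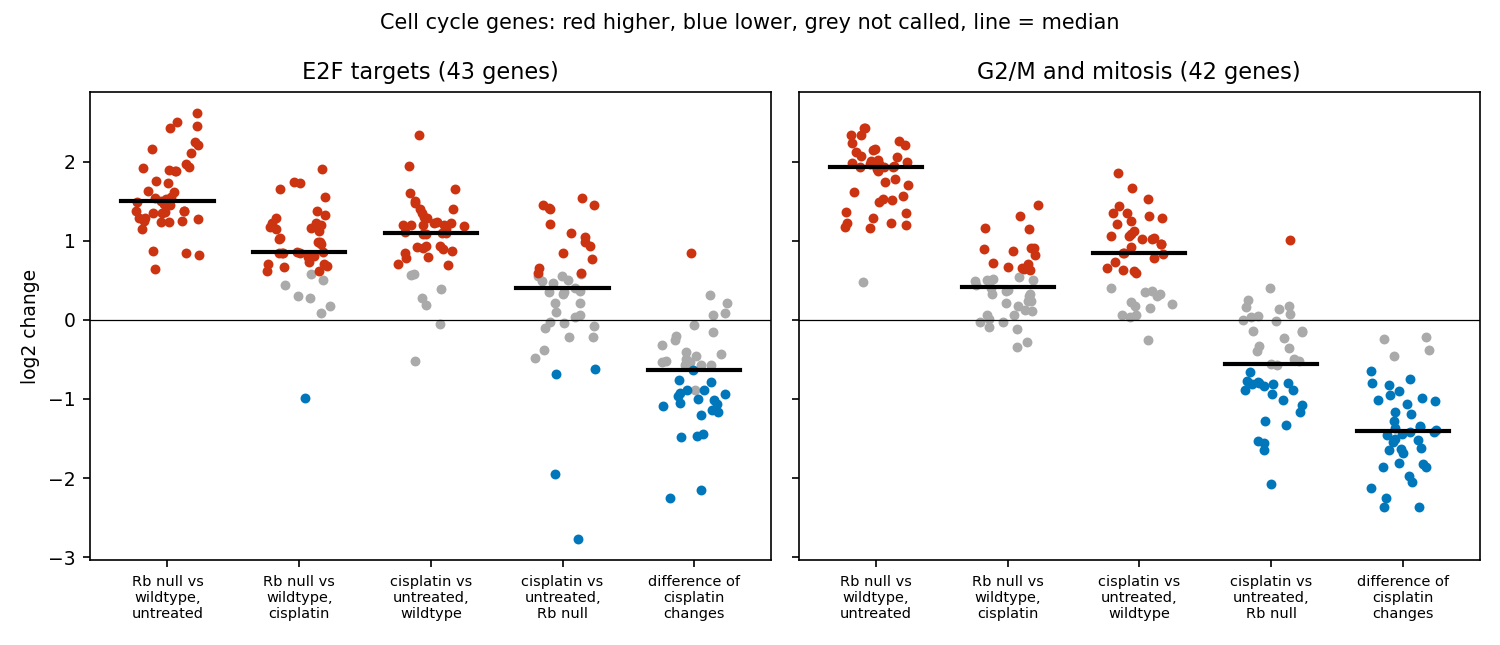
Log2 change (y axis) of each measured member of the E2F target list (43 genes) and of the G2/M list (42 genes) in the 5 comparisons (x axis), where each point is a gene, red if called higher, blue if called lower and grey if not called, and the line is the median. The G2/M median is 0.848 for cisplatin in wildtype and -0.562 for cisplatin in Rb null cells.

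These 4 lists passed with the preset and with an estimated correlation (p53 targets, adjusted p = 4.88e-08 and 0.002; G2/M, 0.000557 and 0.0124; E2F targets, 0.0032 and 0.0271; extracellular matrix, 7.67e-09 and 0.0271). The smooth muscle and TGF-beta list did so too, with 14 of 22 lower and 1 higher (adjusted p = 3.4e-05 and 0.0153), led by the adhesion gene Vcl (log2 -2.07 ± 0.0636). Oxidative stress and metallothionein genes rose, 9 of 20 against 0 that fell (adjusted p = 0.000305 and 0.0271), such as the heme oxygenase gene Hmox1 (log2 1.88 ± 0.0932). So did 8 of 17 heat shock genes against 0 (adjusted p = 0.00184 and 0.0271), such as Hspa1a (3.04 ± 0.13) and Cryab (1.99 ± 0.0952). The ER stress list did not pass (adjusted p = 0.203), with 8 of 28 that rose, such as Atf3 (4.39 ± 0.29) and the phosphatase regulator gene Ppp1r15a (2.54 ± 0.0934), and 13 that fell. With all probe sets of the listed genes it passed as lower (median -0.674, adjusted p = 0.00502). The 3' control probe set of 18S ribosomal RNA was 110.3 ± 10.4 in untreated and 383 ± 91.7 in cisplatin-treated Rb null samples. The 5' probe set went from 16.8 ± 11 to 161 ± 25.6. The actin ratio was 1.15 ± 0.0681 and 1.25 ± 0.0651.

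Calls that were lost with an estimated correlation were those of 5 further lists. Inflammatory cytokines and NF-kB targets rose for 10 of 18 and fell for 4, among them the chemokine gene Cxcl1 (log2 3.55 ± 0.14), the adhesion receptor gene Icam1 (3.13 ± 0.12) and Lif (2.73 ± 0.17). Their list had adjusted p = 0.0351, adjusted p = 0.0859 with an estimated correlation and 0.126 with all probe sets of the listed genes. Immediate early transcripts rose for 16 of 30 and fell for 5, with Fos going from 229 ± 48.5 to 2947 ± 25.4 (adjusted p = 0.000274, and adjusted p = 0.0587 with an estimated correlation). Macrophage and leukocyte markers fell for 14 of 21 and rose for 2, with C1qa at log2 -2.18 ± 0.15 and the perforin relative Mpeg1 at -2.17 ± 0.15 (adjusted p = 0.0032, and adjusted p = 0.0587 with an estimated correlation). Epithelial markers rose for 4 of 7, with the keratin genes Krt19 (log2 2.42 ± 0.16) and Krt18 (2.13 ± 0.23) among them (adjusted p = 0.0329, and adjusted p = 0.0949 with an estimated correlation). Cytosolic ribosomal protein genes lay higher as a list, by a median log2 of 0.30, with 2 of 39 members called higher, Rps25 (1.16 ± 0.0864) being the larger. This list had adjusted p = 0.000125, adjusted p = 0.156 with an estimated correlation and 0.1 under quantile normalization. The other 12 lists tested did not pass (adjusted p from 0.0885 to 0.902). Of these, interferon genes passed without the filter (adjusted p = 0.0339) and with all probe sets (0.0228), and neural markers with all probe sets (0.00416). Medians and tests of the respiratory chain and skeletal muscle lists pointed up and their means, -0.00831 and -0.0053, down; under quantile normalization the respiratory chain median was -0.0148.

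Outside the lists, the guidance gene Slit2 fell from 1916 ± 193 to 65.97 ± 7.05, the growth factor binding gene Igfbp2 from 2052 ± 97.2 to 104 ± 9.51 and Mgll from 3856 ± 130.0 to 201 ± 32.9. The TNF receptor family gene Tnfrsf18 rose from 52.6 ± 6.79 to 1435 ± 41.6 and the nuclear RNA Malat1 by log2 3.72 ± 0.23. In all, 4982 probe sets (36.7%) passed, of which 2141 (43%) were higher and 2841 lower, for 1317 and 1615 genes. With each array centred on its median, 56.3% of 5151 were higher, since this moved the median log2 change of all probe sets from -0.0228 to 0.123.

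**Figure D4:**
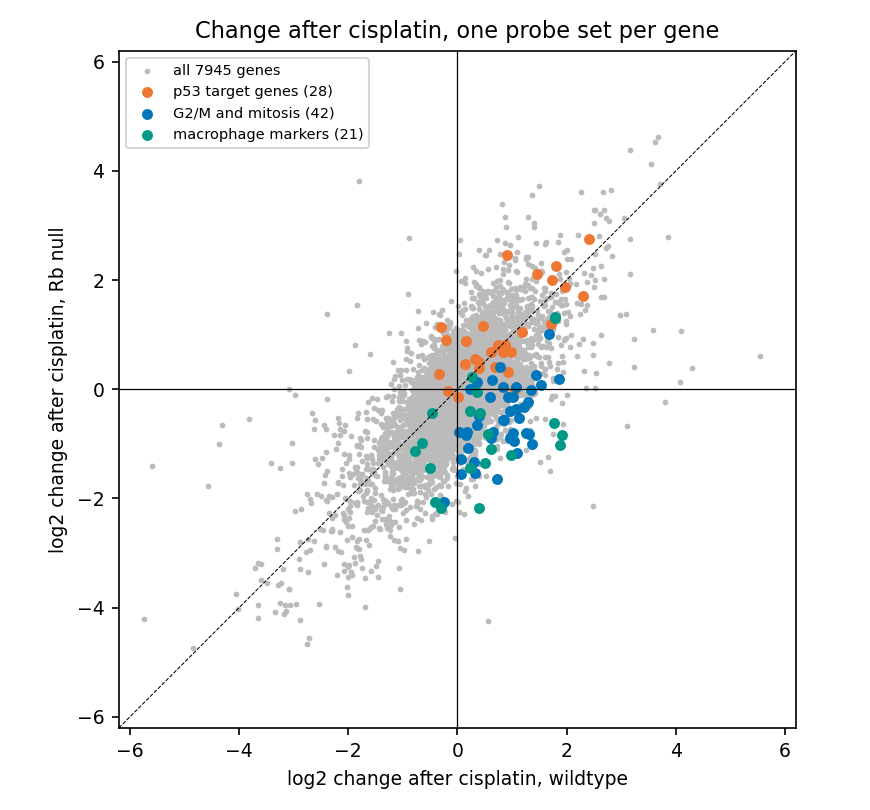
Log2 change after cisplatin in wildtype cells (x axis) and in Rb null cells (y axis), where each point is 1 of 7945 genes, with p53 targets in orange, G2/M genes in blue and macrophage markers in green, and the dashed line marks equal changes. The p53 targets lie mostly above 0 on both axes, while the G2/M and macrophage genes lie mostly below the line.

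The cisplatin responses of the 2 genotypes correlated across 7945 genes at r = 0.707 (Spearman's rho 0.663), where genes are not independent replicates and the 2 responses share no arrays. Of the genes called in both, 672 rose and 755 fell in both, against 195 and 205 by chance, and 66 were called in opposite directions. The difference between the responses, that in Rb null minus that in wildtype cells, asked whether the change with cisplatin differed between the genotypes. A difference cannot be assigned to Rb1 alone, since the untreated wildtype arrays enter it and differ in sex-linked transcripts. Of the mitotic genes, 39 of 42 had their lowest group mean on those arrays. Mitotic genes differed most as a list: the change was lower in Rb null cells for 38 of 42 and higher for 0, by a median log2 of -1.41. Plk1 was at -2.37 ± 0.17, Cenpa at -2.37 ± 0.20 and the ubiquitin-conjugating enzyme gene Ube2c at -2.25 ± 0.12. E2F targets followed for 21 of 43 against 1 (median -0.64), with Pola1 at -2.26 ± 0.21 and the DNA ligase gene Lig1 at -1.48 ± 0.16. The change of macrophage and leukocyte markers was lower for 13 of 21 against 0 (median -1.38), with Lyz2 at -2.90 ± 0.11 and C1qa at -2.58 ± 0.21. That of inflammatory genes was higher for 10 of 18 against 0 (median 0.69), with Cxcl1 at 2.19 ± 0.20, Ccl5 at 2.04 ± 0.29 and Lif at 2.00 ± 0.24.

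These were the 4 lists that passed with the preset and with an estimated correlation (G2/M, adjusted p = 1.04e-19 and 0.000137; E2F targets, 2.2e-08 and 0.002; macrophage markers, 6.63e-08 and 0.00634; inflammatory genes, 4.79e-05 and 0.0104). The list of p53 targets did not pass (adjusted p = 0.0805): 7 of 28 changed more upward in Rb null cells, such as Pmaip1 (log2 1.56 ± 0.15) and Gadd45a (1.44 ± 0.24), and 3 more downward (1 under median centring). The matrix list was lower for 14 of 41 and higher for 0, with Lum at -3.78 ± 0.19 (adjusted p = 0.000363, and adjusted p = 0.106 with an estimated correlation). The ER stress list was higher for 8 of 28 and lower for 4 (2 under median centring), with the stress transcription factor gene Ddit3 at 2.16 ± 0.18 (adjusted p = 0.0187, adjusted p = 0.0587 with an estimated correlation and 0.0515 under quantile normalization). Immediate early transcripts were higher for 10 of 30 and lower for 4 (2 under median centring), with Fosb at 1.12 ± 0.17 (adjusted p = 0.0151, and adjusted p = 0.137 with an estimated correlation). Skeletal muscle markers were higher for 3 of 8, with Actc1 at 1.41 ± 0.21 (adjusted p = 0.00576, and adjusted p = 0.0587 with an estimated correlation). Neural markers were higher for 4 of 10, with Fabp7 at 2.79 ± 0.27 (adjusted p = 0.0186, adjusted p = 0.106 with an estimated correlation and 0.0881 with all probe sets of the listed genes). The ribosomal protein list lay at a median of 0.19 with 1 member higher and 1 lower of 39 (adjusted p = 0.000557, and adjusted p = 0.196 with an estimated correlation). Its direction flipped under quantile normalization, to a median of -0.0202 (adjusted p = 0.669).

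Among single genes the difference of responses was most positive for Lce1f (log2 5.61 ± 0.15), Fxyd6 (4.18 ± 0.25) and Gbp2b (3.76 ± 0.22), and most negative for Rpgrip1 (-4.94 ± 0.26), Tmem45a (-4.79 ± 0.21) and the platelet chemokine gene Ppbp (-4.62 ± 0.14). Some of these sizes and their order rest on groups with very low signals, where the pseudocount sets the value: with 45.8 added in place of 10.4, Fxyd6 was at 3.06, Gbp2b at 2.91 and Tmem45a at -3.52. In all, 3132 probe sets (23.1%) passed, 1173 (37.5%) more positive and 1959 more negative in Rb null cells, for 691 and 1194 genes. With each array centred on its median, 51.6% of 3090 were more positive, as the median over all probe sets moved from -0.0691 to 0.0324. Adjusted over the list alone, the counts were the same for 24 of the 27 lists. Interferon genes then had 5 higher and 6 lower in place of 4 and 5, cholesterol genes 3 lower in place of 4, and chondrocyte markers 3 lower in place of 2. Xist was among the genes that passed (log2 -3.94 ± 0.17); the untreated wildtype samples, which carried Y-linked transcripts and little Xist, enter this difference. The remaining 14 lists tested did not pass (adjusted p from 0.0604 to 0.824). Of these, DNA repair passed as lower and epithelial markers as higher without the filter (adjusted p = 0.0151 and 0.0271) and with all probe sets (0.0354 and 0.0335), and heat shock genes as higher with all probe sets (0.00416).

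**Figure D5:**
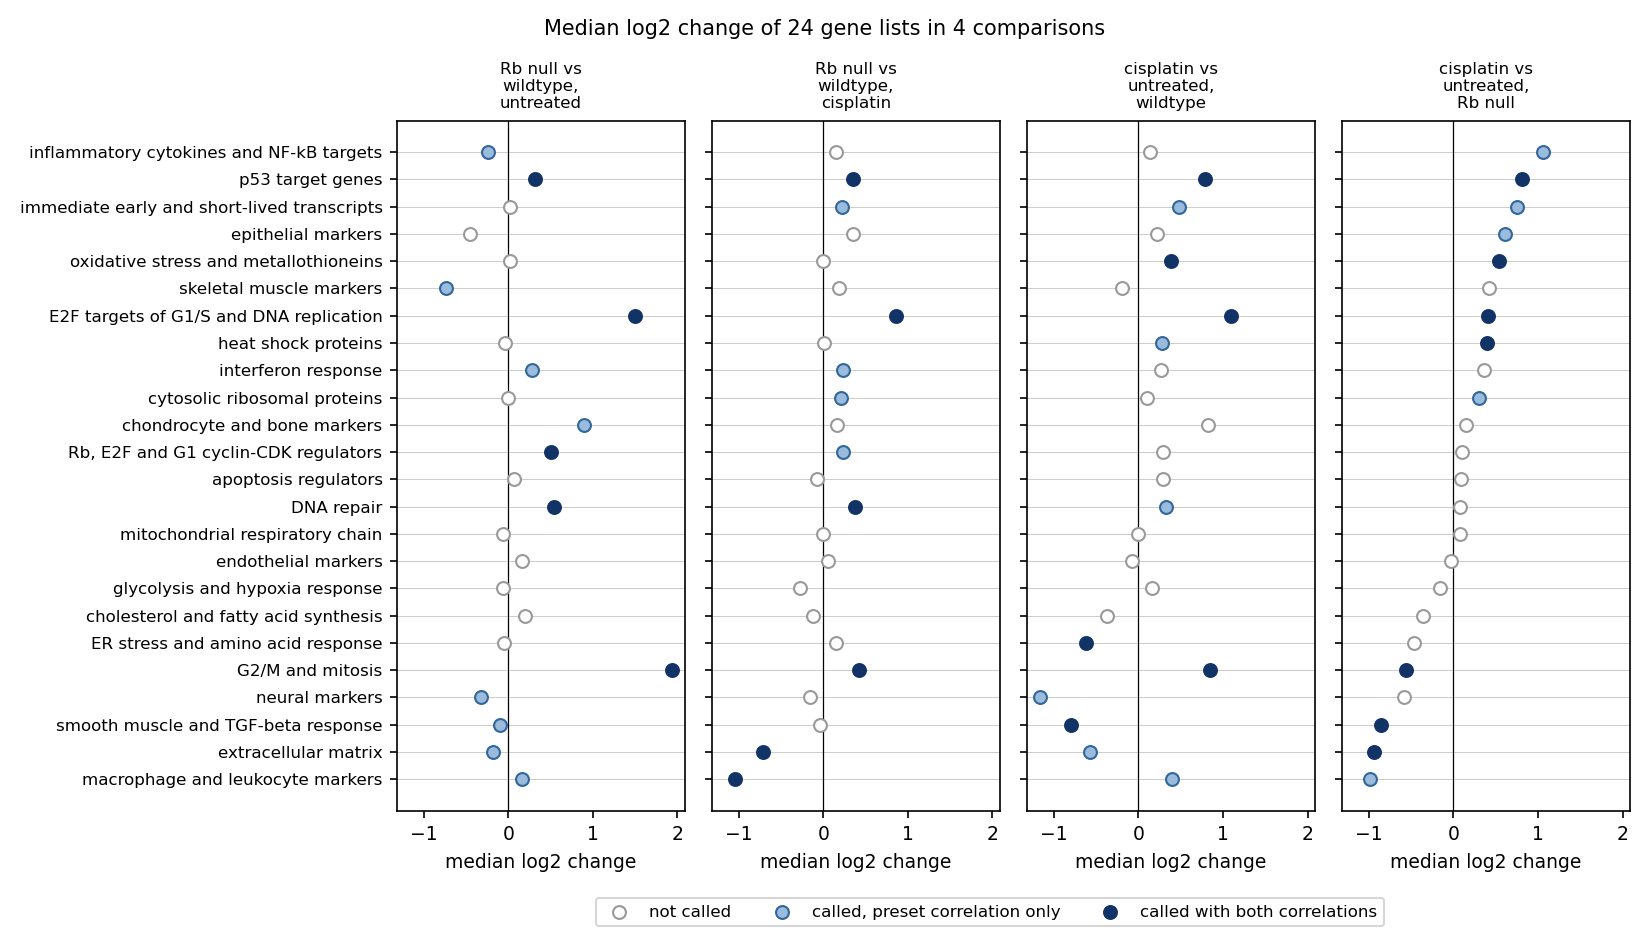
Median log2 change (x axis) of the measured members of each of the 24 lists tested (y axis) in 4 comparisons, where each point is a list, open if it did not pass, light blue if it passed with the preset correlation alone and dark blue if it passed with an estimated correlation too. The p53 targets pass in all 4 comparisons, while the G2/M list is positive for cisplatin in wildtype and negative for cisplatin in Rb null cells.

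Averaged over both treatments, 1545 probe sets differed between the genotypes, 838 higher and 707 lower in Rb null cells. Taking each group as a single sample, which treats the hybridizations of an RNA as repeats, limma called 0 of the 13575 probe sets, with 1486 at an unadjusted p under 0.05. That fit holds only the average effects, so its error is the difference of responses. Such an error cannot be told apart from a spread between cultures. Averaged over both genotypes, 3940 probe sets changed with cisplatin, 1789 (45.4%) higher and 2151 lower. With each array centred on its median, 55.8% of 4044 were higher. With each group as a single sample 1911 were called, of which 1910 were among the 3940.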

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

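The tests of the Xist and Y-linked pattern, those of the mitotic pattern in Rb null cells and in the untreated wildtype culture, and that of the share of macrophages were chosen after the results were seen. The tests of between-array scaling and of other splits were chosen before.

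Transcripts of the sex chromosomes differed between the untreated wildtype arrays and all others, which the design does not name: Eif2s3y, below the filter on level over all arrays, had a mean signal of 478.1 there. All 8 probe sets of Xist and of Y-linked genes with a group mean above 100 separated the 3 untreated wildtype arrays from the other 9, but this restates the pattern and does not test cells of the other sex as its cause. A sample of Rb null cells under the untreated wildtype label was argued against by Rb1, whose lowest signal on the untreated wildtype arrays was 4 times the highest on any Rb null array. A loss of Y-linked expression in culture as the whole cause was argued against by Xist, which such a loss would leave unchanged and which was higher by log2 4.08 in cisplatin-treated than in untreated wildtype cells. An effect of cisplatin on Xist could not be judged from Rb null cells, where Xist was high before treatment and changed by log2 0.135. Such an effect, as the whole cause, would also have to lower the Y-linked signals in wildtype cells. Eif2s3y went from 478 to 1.27, Kdm5d from 193 to 21.5 and Uty from 199 to 27.4 there. Embryos of different sex for the 2 wildtype groups would give both changes, but the labels do not state the sex. This explanation stays open, and a wrong label within the wildtype cells was not tested.

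Mitotic transcripts were higher in cisplatin-treated than in untreated wildtype cells, by a median log2 of 0.848. The choice of between-array scaling made little difference, as the lowest median under quantile normalization and median centring was 0.835. These alternatives moved the median over all probe sets only from 0.0383 to 0.0377 and 0.0825. They could thus hardly have removed a shift of this size, and draw no line between scaling and other causes. A rise of mitotic transcripts with cisplatin whatever the genotype was argued against by the median of -0.562 in Rb null cells. An untreated wildtype culture that differs in more than treatment stays open: 39 of the 42 members had their lowest group mean there, which a cisplatin response would give as well, and the sex-linked transcripts of that group differ too, so treatment and culture cannot be told apart. A response of Rb1-containing cells to cisplatin remains possible, as the design gives genotype as a factor, but it was not tested apart from the culture.

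Macrophage and leukocyte markers were lower in Rb null than in wildtype cells after cisplatin, by a median log2 of -1.05. The choice of between-array scaling made little difference, as the highest median under both scaling alternatives was -0.96. These moved the median over all probe sets only from -0.0427 to -0.0132 and 0.0254, so they could hardly have removed a difference of this size. A different share of macrophages in the cultures, for which no sort is described, cannot be told apart from regulation within the fibroblasts. Of the 5 markers with the highest signal in cisplatin-treated wildtype cells, 3 were called lower (Lyz1 at 5494 ± 265 against 1481 ± 205, Lyz2 at 4174 ± 254 against 1087 ± 34.5, Ctss at 1039 ± 139 against 195.7 ± 40.4; SD, n = 3), while Cd14 (1568 ± 70.8 against 1712 ± 74.7) and Csf1r (1527 ± 70.0 against 1688 ± 59.9) were not. The Lyz1 probe set is of a type that can cross-hybridize, and its difference (log2 -1.89) lay near that of Lyz2 (-1.93). Lyz1 and Lyz2 may therefore not count as separate markers. Fewer macrophages in the cisplatin-treated Rb null culture may contribute, with genotype open beside it. Of the 21 markers 0 are on another list, and how many of them fibroblasts express is not known from these data.

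The cisplatin effect differed between Rb null and wildtype cells, by limma's test of the difference itself, for 3132 probe sets and 10 lists. With an estimated correlation 4 of these lists passed (E2F targets, G2/M, inflammatory genes and macrophage markers), and the other 6 did not (adjusted p from 0.0587 to 0.196). The median log2 differences (Rb null minus wildtype) of lists were -0.638 for E2F targets, -1.41 for G2/M, -0.27 for extracellular matrix, 0.686 for inflammatory genes, 0.205 for ER stress, and 0.228 for immediate early transcripts. They were 0.191 for cytosolic ribosomal proteins (-0.0202 under quantile normalization), 0.804 for skeletal muscle, -1.38 for macrophage and 0.24 for neural markers. The single genes with the largest differences, whose sizes depend on the pseudocount where a group is very low, were Lce1f (5.607), Fxyd6 (4.184), Gbp2b (3.759), Cd200 (3.66), Ifi202b (3.653) and Crct1 (3.376) on the positive side and Rpgrip1 (-4.939), Tmem45a (-4.788), Ppbp (-4.625), Sod3 (-4.031), Xist (-3.945) and Aqp1 (-3.906) on the negative. The 3' control probe set of 18S ribosomal RNA, which no comparison used, had mean signals of 213.5 in cisplatin-treated wildtype and 383 in cisplatin-treated Rb null samples, against 105.7 and 110.3 without cisplatin. The 5' probe set went from 14.4 to 51.9 with cisplatin in wildtype and from 16.8 to 161 in Rb null samples. The middle one went from 23.5 to 49.3 and from 14.7 to 126.9.

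Regrouping the arrays tests only the spread between hybridizations, since the design describes 1 RNA sample per group, and says nothing about chance differences between cultures. Within that limit, 100 random regroupings, the real one included, exchanged genotype labels within each treatment. The real grouping gave the largest count for the difference of responses (1 of 100 as large, 3132 probe sets, highest other 2648). The same held for the average genotype effect (1545, highest other 662). It held for the average cisplatin effect (3940, highest other 2112), with treatment labels exchanged within each genotype. Exchanging genotype labels sets the real groups against no genotype difference of any kind, not against equal responses to cisplatin. Hybridizations of a group were much alike, so mixing groups adds spread and loses calls whatever the cause of a difference. With each group as a single sample, limma called 0 probe sets for the average genotype effect (1486 at an unadjusted p under 0.05) and 1911 for that of cisplatin. The error of that fit is the difference of responses, which cannot be told apart from a spread between cultures. For comparisons of 3 with 3 arrays there are 10 splits, too few for a share under 0.05. The real counts and the highest of the other splits were 1678 and 1 for genotype without cisplatin, 3002 and 0 for genotype with cisplatin, 3626 and 0 for cisplatin in wildtype and 4982 and 0 for cisplatin in Rb null cells.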

How the results depend on the processing

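The fit without the untreated wildtype group was chosen after the data were seen; all other alternatives were planned. In the order genotype without and with cisplatin, cisplatin in wildtype and in Rb null cells, difference of responses, average genotype and average cisplatin effect, the counts of called probe sets were 1078, 1906, 2297, 3257, 2021, 958 and 2527 with the lowest 60% left out, where fewer probe sets were tested. They were 4598, 6968, 7413, 8756, 5109, 6906 and 9314 with no minimum fold, and 598, 928, 1581, 2352, 1191, 447 and 1706 at 2-fold or more, by construction of the limit. With each group as a single sample, limma called 0 for the average genotype effect (1486 at an unadjusted p under 0.05) and 1911 for that of cisplatin, with a single residual degree of freedom in place of 8. That degree of freedom is the difference of responses, so the fit gives no separate measure of the spread between cultures. Of the tests of lists 28 in place of 57 passed with an estimated correlation. Without the filter the 2 correlations across genes were 0.644 and 0.205, where 12393 genes entered; the cause was not tested. All other counts stayed within 1.5 times the main count, among them 2995 and 4988 for genotype with cisplatin and cisplatin in Rb null cells without the untreated wildtype group. Neither comparison uses that group, so its removal could change only the pooled spread. It does not test the difference in sex-linked transcripts, which enters the comparisons that use the group. Leaving out each array in turn gave 1644 to 1732, 3002 to 3057, 3582 to 3680, 4944 to 5027, 2998 to 3160, 1529 to 1568 and 3931 to 3978. Of 494 values of named genes 453 kept their call under the alternatives run on single genes, which leave out the fold minimum, 41 lost or gained it under some and 0 changed direction while called.

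With the replicate label as a block the counts were 1685 and 3008 for genotype without and with cisplatin, 3061 for the difference of responses and 1544 for the average genotype effect. Deviations from the group means of arrays with the same label correlated between genotypes at -0.159, 0.109 and -0.186 (labels 1 to 3) and at -0.021, 0.0835 and -0.000859 (a to c), so the labels do not pair the hybridizations. No paired analysis was possible for the cisplatin comparisons because treated and untreated arrays carry different labels. Signal over background could not be judged, as detection calls were not among the values used here.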

Other observations

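The tests on very long genes and on the neighbours of Rb1 were written down before their results were computed. The hypothesis on very long genes was formed after seeing the data.

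Single genes of metabolism and apoptosis changed after cisplatin, in lists that did not pass as a whole at the main settings. For scale, 2932 of all 7945 genes were called after cisplatin in Rb null cells and 2184 in wildtype cells. The apoptosis list held no larger share of called genes than that in either genotype. Of 22 genes of glycolysis and the hypoxia response, 9 fell and 3 rose after cisplatin in Rb null cells, with the vasodilator peptide gene Adm at log2 -1.60 ± 0.0921 and the lactate transporter gene Slc16a3 at -1.26 ± 0.13. The oxygen sensor gene Egln3 rose (1.38 ± 0.10; list adjusted p = 0.342). In wildtype cells 5 fell and 4 rose, with the collagen prolyl hydroxylase genes P4ha2 at -1.08 ± 0.0837 and P4ha1 at -1.06 ± 0.0779 (list adjusted p = 0.845). Of 21 genes of cholesterol and fatty acid synthesis, 7 fell and 3 rose in Rb null cells, among them the elongase gene Elovl6 (-1.82 ± 0.13) and the mevalonate kinase gene Mvk (-1.35 ± 0.23). The list's adjusted p was 0.116, but 0.033 without the filter and 0.00775 with all probe sets of the listed genes. In wildtype cells 5 of these genes fell and 1 rose (list adjusted p = 0.106, but 0.0256 with all probe sets). The apoptosis list held 6 that rose and 4 that fell of 28 in Rb null cells, with Pmaip1 at 2.47 ± 0.11 and the caspase gene Casp6 at 1.65 ± 0.10 against the survival gene Bcl2 at -1.23 ± 0.25 (list adjusted p = 0.308, but 0.00644 with all probe sets; 2 fell under median centring). In wildtype cells 5 rose and 1 fell, with Bbc3 at 0.99 ± 0.10 and Bcl2 at -1.08 ± 0.25 (list adjusted p = 0.0623, but 0.0319 without the filter and 0.00233 with all probe sets).

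Markers of other cell types with few measured members changed in both genotypes after cisplatin. The endothelial receptor gene Flt1 fell (log2 -2.19 ± 0.11 in wildtype and -1.72 ± 0.11 in Rb null cells). The endothelial adhesion gene Esam rose (0.90 ± 0.23 and 1.31 ± 0.23), in a list of 6 that did not pass (adjusted p = 0.841 and 0.902). Of 4 measured adipocyte markers, too few for a test, Cebpa rose (1.99 ± 0.13 and 2.15 ± 0.13) and Lpl fell (-0.72 ± 0.18 and -0.71 ± 0.18), a call lost under 2 alternatives in each genotype. The keratin gene Krt18 rose in wildtype cells too, by 2.31 ± 0.23.

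A hypothesis formed from names among the largest falls, which were not counted or tested for length, was that very long genes may fall as a class after cisplatin. A list of 44 other very long genes was written from general knowledge, of which 15 were measured. Their median log2 change was -0.767 in wildtype and -1.51 in Rb null cells, against 0.00221 and -0.0723 in 10000 random lists matched on level. These medians lay at percentile 0 and percentile 0.01 of those lists. In wildtype cells 8 fell and 0 rose, and in Rb null cells 10 fell and 0 rose by limma's test, among them Exoc4 (-3.49 and -3.55), Dock1 (-2.95 and -3.93), Pard3 (-1.98 and -2.25) and Dmd (-1.48 and -1.59). The list is small, and gene length was not compared across genes, although gene positions were at hand. The values are those that a fall of very long genes would give, without showing how it depends on length.

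A targeted allele carries a segment of chromosome around it that could differ between genotypes. Of the 20 measured genes nearest to Rb1 on its chromosome, 0% were called in the same direction in both genotype comparisons by limma, against 4.69% of all genes and 15% at the 95th percentile of windows of 20 genes. At an unadjusted p under 0.05 in both comparisons, 15% of the 20 went the same way, against 21.2% of all genes. By the bound set before the result was seen, no excess of genotype differences lay near Rb1. The test covers expression only, so a segment that leaves the expression of its genes unchanged stays open.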
